A study of Mus musculus with 6 samples.

How the data were processed

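RNA from mouse cerebellum collected at postnatal day 7 was measured on 6 expression arrays. The labels put 3 arrays in the wild-type group (Math1Cre, with wild-type Crebbp) and 3 in the knockout group (Math1Cre with both Crebbp alleles floxed). Per the labels' protocols, total RNA was extracted with Trizol and labelled with the GeneChip WT PLUS kit. The deposited values are log2 expression values, one per probe set and array. RMA and oligo are named in the submitters' processing notes, without versions. The array design, its build and any filter applied before deposit are not given in the sources used here. The deposited log2 values were used as they stood, with no further background correction or normalization. Their medians were 7.26, 7.25 and 7.26 on the wild-type arrays and 7.29, 7.25 and 7.29 on the knockout arrays, and over all probe sets and arrays the 25th and 75th percentiles were 6.02 and 8.86. No measure of signal over background came with the values, so dim genes have no detection call. With 3 arrays per group, the number of arrays limits the precision.

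The table held 41345 probe sets. GEO's platform annotation gave 1 gene symbol to 23521 of them, several to 1814 and none to 16010. Through the Entrez identifier, 23328 were found in the mouse gene table (assembly GRCm38.p6), and 0 symbols needed an update. That table served only for names and for which genes neighbour each other. Probe sets with several symbols or none were named after no gene. For each gene the probe set with the highest mean over the 6 arrays was tested, which gave 22180 genes, 1082 of them with more than 1 probe set. Among the genes past the threshold, 92 had another probe set, and 88 of these 113 other probe sets had the same sign. 1 had the opposite sign and passed the threshold itself.

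The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a prior variance that follows mean brightness). Tests were two-sided, and p-values were adjusted by Benjamini-Hochberg over the 22180 genes. A gene passed at an adjusted p under 0.05. "Rose" and "fell" are used only for genes that passed. Fold changes are knockout minus wild type on the log2 scale, with the standard error (SE) of the fit. No label says that the arrays of a group come from separate animals, so p-values measure only the spread between these samples, part of which may be technical. The sex-linked genes show more than 1 animal in each group, but not whether every array had its own.

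20 gene lists were fixed before the data were examined: granule neuron stages, the other cell types of the cerebellum, tissues that can come along at dissection, and pathways linked to neuronal maturation or to CREBBP. Each was tested with limma's camera at a preset correlation of 0.01, adjusted over the 20 lists. Camera asks whether a list's genes moved relative to all other genes. It was run again with an estimated correlation between genes, and fry, which asks whether a list's genes move one way on balance, was run beside it. Counts "adjusted over the list alone" use the p-values of the list's own members. The genes named in the text also follow a rule fixed beforehand. It takes Crebbp, the 12 largest rises and 12 largest falls among genes that passed and whose groups did not overlap (leaving out predicted genes and microRNA, small nuclear and small nucleolar RNA genes), the 3 of these with the smallest p in each direction, and up to 4 members of each list with the smallest p. A gene named outside this rule is said to be so.

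The fit was tested on simulated values for 22180 genes with the spread of the real arrays. It recovered 19.4% of 67 genes shifted by 0.3 (log2), 46.3% of 67 shifted by 0.5 and 92.4% of 66 shifted by 1, and called 0.0136% of 21980 genes left alone. Genes varied independently there, and far fewer were shifted than passed in the real comparison, so these shares are a rough guide. Camera called 100% of 20 sets of 20 genes shifted by -0.3 and 0 of 100 sets left alone, in a simulation where genes vary independently. The estimated correlation in the real lists ran from -0.01 (activity and CREB targets) to 0.91 (choroid plexus). It was 0.17 and 0.37 for the early and maturing granule neuron lists. The simulation therefore says little about false calls in the real lists.

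Alternatives listed before the data were examined were a prior variance without a trend, a robust prior, dim genes left out, median centring, repeated quantile normalization, array weights, the replicate number as a block, each probe set tested on its own, 2 other thresholds, and each array left out in turn. After the choroid plexus genes had been seen to differ between arrays, 3 more were added: the mean of those genes as a covariate, the Xist value as a covariate, and a fit without the 3 arrays on which the choroid plexus gene Ttr lay above 10. Tables were handled in Python 3.11.15 with pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.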

Results

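Expression was measured in 6 samples of whole mouse cerebellum taken at postnatal day 7, when granule neuron precursors in the outer layer of the cerebellum still divide while their daughters migrate inward and mature. Math1 (Atoh1) is expressed in granule neuron precursors, and Cre driven by it removes the floxed part of Crebbp in that lineage. CREBBP is a lysine acetyltransferase and a coactivator of CREB and many other transcription factors. The comparison asks how its loss from this lineage changes gene expression during cerebellar development. The correlation between arrays of a group was 0.990 to 0.992 over 6 pairs, and between arrays of different groups 0.987 to 0.990 over 9 pairs (Pearson's r across probe sets, which are not independent). The first principal component held 39.1% of the variance, with the 3 wild-type arrays at -16.1 to -9.64 and the 3 knockout arrays at 8.76 to 18.8.

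Crebbp itself was lower in the knockout. Its log2 value was 11.95 ± 0.05 in wild type and 11.40 ± 0.07 in knockout (SD, n = 3 each), a log2 fold change of -0.56 (SE 0.05, limma adjusted p = 0.000354), or 1.47-fold with a 95% confidence interval of 1.36 to 1.59. The wild-type arrays read 11.96, 11.99 and 11.90 and the knockout arrays 11.46, 11.42 and 11.32, so every array lay on the side its label gives. Whether the probe set covers the deleted part of the gene is not given in the sources used here, and whole cerebellum holds cells outside the Math1 lineage, so the remaining signal is no measure of how much Crebbp was removed.

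Of 22180 genes, 604 rose and 875 fell in the knockout. The changes were mostly small: the median absolute log2 change of the 1479 genes was 0.35, a 1.27-fold change, and 12 genes rose and 14 fell by at least 2-fold. Genes whose 3 values in one group all lay apart from the other group made up 24.96% of those tested, where chance gives 10%, and included every gene past the threshold. The median SD within a group was 0.08 in wild type and 0.09 in knockout. The counts moved by over 1.5 times with single arrays: 199 rose and 366 fell without wild-type replicate 1, 309 and 462 without wild-type replicate 2, and 317 and 528 without knockout replicate 1. Without the 3 arrays with high choroid plexus values, described below with the other cell types, 112 rose and 124 fell.

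Leaving out predicted and small RNA genes, as the rule for named genes does, the largest rises included secreted and matrix proteins, a meiotic cohesin and an interferon. Eln, the elastic fibre protein elastin, rose from 8.29 ± 0.10 to 9.75 ± 0.12 (log2 change 1.46, SE 0.08, adjusted p = 1.86e-05). Rec8, the meiotic cohesin subunit, rose by 1.39 (SE 0.14), the cytochrome P450 gene Cyp4f13 by 1.12 (SE 0.10), Ly86, the partner of an innate immune receptor, by 1.06 (SE 0.10), and the monooxygenase gene Moxd1 by 1.05 (SE 0.13). Chrna3, a nicotinic acetylcholine receptor subunit, had the smallest p among the rises of these genes, from 11.34 ± 0.04 to 12.14 ± 0.01 (log2 change 0.80, SE 0.04, adjusted p = 1.86e-05). It was followed by Eln and by Cyp11a1, the enzyme that starts steroid synthesis from cholesterol, at 0.91 (SE 0.06). AA388235 rose by 1.40, Fam205a2 by 0.99, the tachykinin gene Tac2 by 0.96 and the interferon gene Ifna4 by 0.93. Other probe sets of Fam205a2 changed by 0.87, 0.87, 0.99 and 1.48 and passed when tested on their own. The changes of 0.87 are identical, and that of 0.99 equals the tested probe set's, so these may share probes. The 3 other large rises lost their call without certain arrays, though their changes stayed similar in those fits. With each array left out in turn, the change ran from 0.75 to 1.47 for Fxyd1. It ran from 0.72 to 1.16 for Prelp and from 0.73 to 1.34 for Pisd-ps3. Fxyd1, a regulator of the sodium pump, rose by 1.12 (SE 0.27, adjusted p = 0.0390), but its adjusted p was 0.116, 0.130, 0.0798 and 0.0936 without wild-type replicate 1, 2 or 3 or knockout replicate 1 (changes of 1.16, 1.05, 1.15 and 1.13), and its change was 0.45 without the arrays with high choroid plexus values. Prelp, a matrix proteoglycan, rose by 0.93, with an adjusted p of 0.0586, 0.0654 and 0.0509 without wild-type replicate 1 or 2 or knockout replicate 1 (changes of 0.96, 0.84 and 0.90), and a change of 0.49 without the arrays with high choroid plexus values. Another probe set of Prelp changed by -0.22 and did not pass (adjusted p = 0.308). Pisd-ps3 rose by 1.12, with an adjusted p of 0.0735, 0.125 and 0.0958 without wild-type replicate 1, knockout replicate 1 or knockout replicate 3 (changes of 1.28, 0.997 and 1.04). Tac2 reached an adjusted p of 0.0591 with the choroid plexus mean as a covariate.

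Among the same genes, the interferon-inducible gene Mndal had the largest measured fall, from 7.52 ± 0.08 to 5.64 ± 0.45 (log2 change -1.89, SE 0.19, adjusted p = 0.000568). Its knockout mean lay below the 25th percentile of all probe sets (6.02) and has no detection call, so the size of this fall is uncertain. Cxcl14, a chemokine, fell by 1.31 (SE 0.08), Epha3, an ephrin receptor that guides axons, by 1.13 (SE 0.07), Erbb4, a neuregulin receptor, by 1.07 (SE 0.07), Lgr5, an R-spondin receptor, by 0.999 (SE 0.08), and St18, a zinc finger transcription factor, by 0.96 (SE 0.05). St18 had the smallest p of all genes that fell (adjusted p = 1.86e-05), followed by Peli2, a ubiquitin ligase of immune signalling, which fell by 0.75 (SE 0.04), and Cntn2, a cell adhesion protein of young granule neurons, which fell by 0.77 (SE 0.05). Dmrta1 fell by 1.16, Rgs13, a regulator of G protein signalling, by 1.08, Erdr1 by 1.10 and Ahcy, the enzyme that hydrolyses S-adenosylhomocysteine, by 1.13. Another probe set of Ahcy read 0.32 higher in knockout and did not pass (adjusted p = 0.269), and another of Lgr5 changed by -0.15 (adjusted p = 0.565). Mid1 fell by 1.503 (SE 0.30), with an adjusted p of 0.0554 without wild-type replicate 2 and 0.0627 with the choroid plexus mean as a covariate, and another of its probe sets changed by -0.78 and did not pass (adjusted p = 0.236). Zfp457 fell by 1.23 (SE 0.24) from a low mean of 5.76, with an adjusted p of 0.0641 without wild-type replicate 2, 0.0511 without knockout replicate 1 and 0.123 with that covariate.

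**Figure D1:**
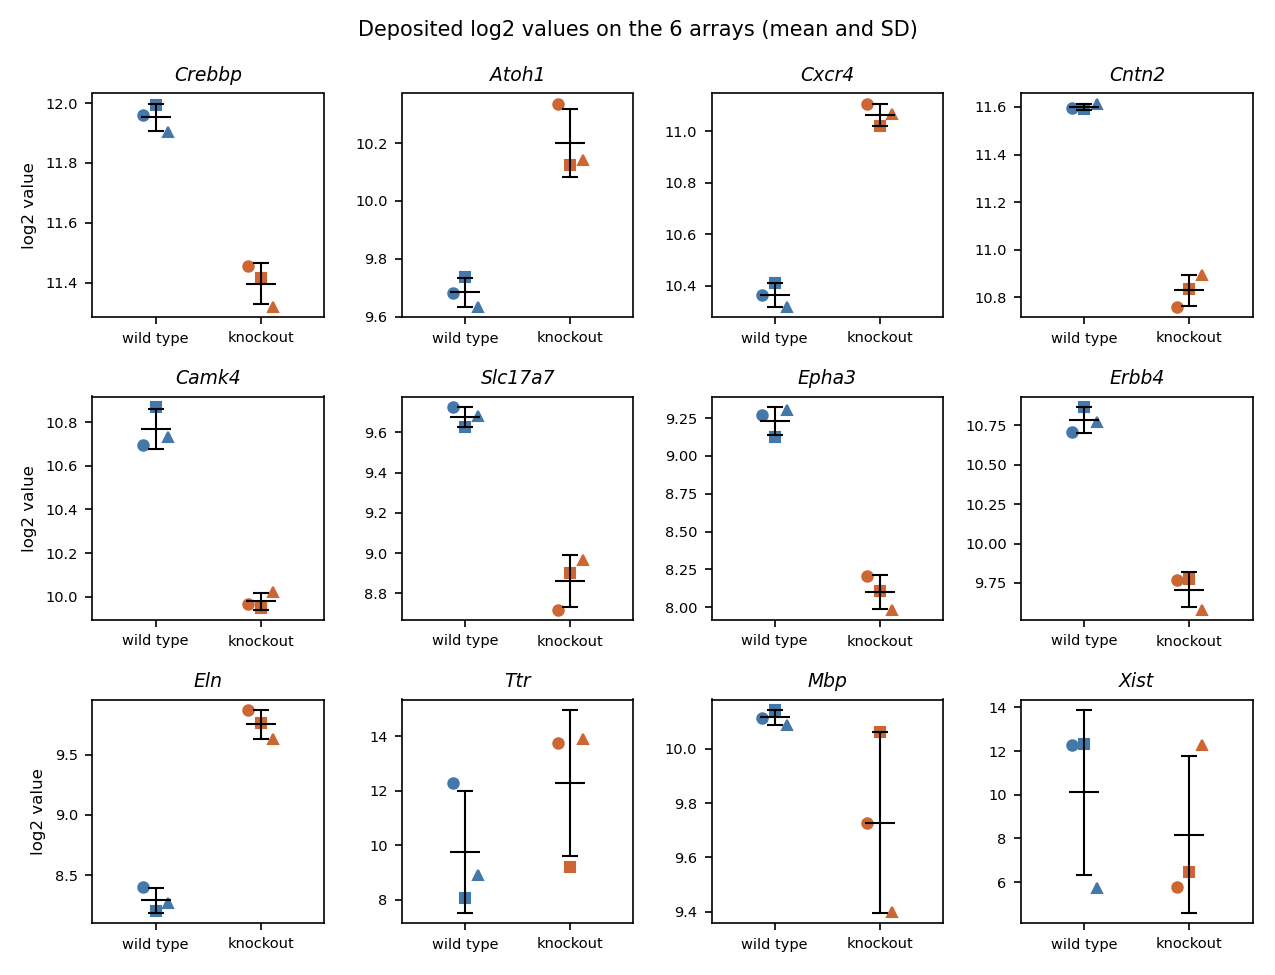
Deposited log2 values of 12 genes on the 6 arrays, with wild type in blue and knockout in orange; circles, squares and triangles are replicates 1, 2 and 3, and bars give the mean and SD of each group. Crebbp and the 8 genes from Atoh1 to Eln separate the groups on every array, while Ttr and Mbp spread widely within the knockout group and Xist splits both groups. For Mbp, too, every knockout array reads below every wild-type array, but it did not pass (limma adjusted p = 0.117).

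In the list of precursor and SHH pathway genes, 3 of 14 measured members rose, 2 fell and 9 did not pass. Cxcr4, the chemokine receptor that holds precursors in the outer layer, rose from 10.36 ± 0.05 to 11.06 ± 0.04 (log2 change 0.70, SE 0.05, adjusted p = 6.79e-05), and Atoh1, the transcription factor of the precursor state, rose by 0.52 (SE 0.06, adjusted p = 0.00191). The third rise was Ccnd1 (cyclin D1), at 0.24, named here outside the rule. Its call was lost when wild-type replicate 1, 2 or 3 or knockout replicate 1 or 2 was left out. Cxcr4 and Atoh1 passed whichever array was left out. Sfrp1, a secreted Wnt antagonist, fell by 0.64 and Ccnd2 (cyclin D2) by 0.33. Adjusted over the list alone, 4 rose and 2 fell. The list did not pass as a whole (median 0.08, camera adjusted p = 0.0790, 0.446 with an estimated correlation), but passed upward after repeated quantile normalization (camera adjusted p = 0.0436). Without knockout replicate 3 its adjusted p was 0.0223, and without wild-type replicate 1 the call of Ccnd2 was lost (adjusted p = 0.0779), leaving 1 fall. Without the arrays with high choroid plexus values Atoh1 changed by 0.44 (adjusted p = 0.0667).

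Genes of early and migrating granule neurons were lower in the knockout: 12 of 19 fell, 1 rose and 6 did not pass. Cntn2 fell by 0.77, Plxna2, a semaphorin receptor subunit in migrating granule neurons, by 0.63 and Nfix, a nuclear factor I transcription factor, by 0.39. The netrin receptor gene Dcc rose by 0.57 (SE 0.04, adjusted p = 0.000189). The list's median was -0.24 and its mean was lower on every knockout array (-0.24, -0.20 and -0.27) than on any wild-type array (0.02, 0.02 and -0.04). Its camera adjusted p was 6.56e-11, but 0.324 with an estimated correlation, and fry's was 0.0143. Adjusted over the list alone, 15 fell and 1 rose. The number that fell was 5, 7 and 6 without wild-type replicate 1, wild-type replicate 2 and knockout replicate 1, with medians of -0.23, -0.21 and -0.25. It was 2 without the arrays with high choroid plexus values, a fit that holds 1 knockout array, where the median was -0.21 (camera adjusted p = 5.23e-06).

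Genes of maturing granule neurons were lower too, with 8 of 18 past the threshold, 0 rises and 10 that did not pass. Slc17a7, the vesicular glutamate transporter of granule neurons, fell from 9.68 ± 0.05 to 8.86 ± 0.13 (log2 change -0.81, SE 0.07, adjusted p = 0.000286). Camk4, a calcium-dependent kinase that acts on CREB, fell by 0.79, Fat2, an atypical cadherin of granule neurons, by 0.79 and Rbfox3, which encodes the neuronal nuclear protein NeuN, by 0.52. Another probe set of Camk4 changed by -0.32 and did not pass (adjusted p = 0.130). Gabra6, the GABA receptor subunit that marks mature granule neurons and is named here outside the rule, had a change of -0.997 that did not pass (SE 0.28, adjusted p = 0.0627). The list's median was -0.28 (camera adjusted p = 1.96e-09, 0.324 with an estimated correlation, fry 0.0333), and adjusted over the list alone 14 fell and 1 rose. Without the arrays with high choroid plexus values 4 fell, with a median of -0.31 (camera adjusted p = 1.66e-08).

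Of 19 synaptic vesicle and release genes, 9 fell, 0 rose and 10 did not pass. Among them the vesicle protein Sv2b fell by 0.68, Vamp1 by 0.41, the release regulator Cplx1 by 0.32 and the fusion protein Snap25 by 0.28 (median of the list -0.27, camera adjusted p = 1.65e-09, 0.341 with an estimated correlation, fry 0.0477). Of 15 glutamate and GABA receptor genes, 6 fell, 0 rose and 9 did not pass. Grm5, a metabotropic glutamate receptor, fell by 0.93 (SE 0.11), the NMDA receptor subunits Grin2a and Grin2b by 0.67 and 0.44 and the kainate receptor subunit Grik2 by 0.44 (median -0.25, camera adjusted p = 6.35e-07, 0.324 with an estimated correlation, fry 0.0333). Another probe set of Grin2b changed by -0.08 and did not pass. Adjusted over the list alone, 13 vesicle genes fell and 0 rose, and 9 receptor genes fell and 1 rose. Without the arrays with high choroid plexus values 1 vesicle gene and 2 receptor genes fell, with medians of -0.19 and -0.25 (camera adjusted p = 2.29e-05 and 3.25e-06).

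Of 32 axon guidance and adhesion genes, 8 fell, 1 rose and 23 did not pass. Epha3 fell by 1.13, the netrin receptor Unc5b by 0.63 and the cadherins Cdh8 and Cdh7 by 0.63 and 0.42. The gene that rose, named outside the rule, was Ntn1, which encodes the ligand netrin-1, at 0.26. The list's median was -0.13 (camera adjusted p = 1.04e-05, 0.368 with an estimated correlation, fry 0.0678), and adjusted over the list alone 12 fell and 1 rose. Without wild-type replicate 1, 5 fell, with a median of -0.11, and without knockout replicate 3 the median was -0.06. Ntn1 passed with all 6 arrays, while 0 members rose when wild-type replicate 1, 2 or 3 or knockout replicate 1 or 2 was left out, and 2 rose without knockout replicate 3. Without the arrays with high choroid plexus values 3 fell, with a median of -0.07 (camera adjusted p = 0.00124).

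**Figure D2:**
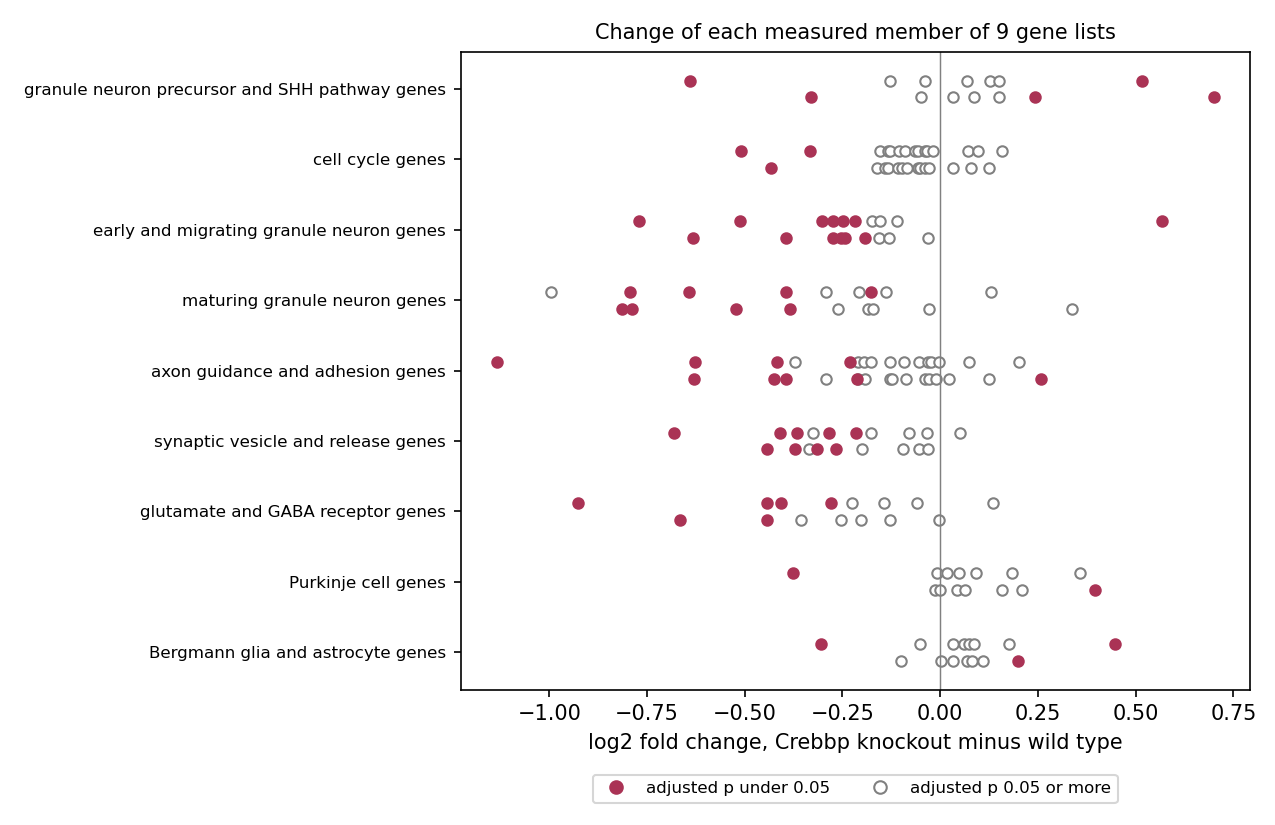
Log2 fold change (knockout minus wild type) of every measured member of 9 gene lists; filled points passed an adjusted p of 0.05 and open points did not. Members of the early, maturing, synaptic vesicle and receptor lists lie mostly below 0, with medians of -0.24, -0.28, -0.27 and -0.25, while those of the precursor list go both ways.

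Of 29 cell cycle genes, 3 fell, 0 rose and 26 did not pass. The transcription factors E2f2 and E2f1 fell by 0.51 and 0.43 and the replication licensing factor Cdt1 by 0.33. Pcna had a change of -0.16 (adjusted p = 0.0730), and the proliferation marker Mki67, named outside the rule, one of -0.14 (adjusted p = 0.132). The median was -0.06 (camera adjusted p = 0.00374, 0.446 with an estimated correlation, fry 0.172), and adjusted over the list alone 4 fell and 0 rose. With 1 array left out the median ran from -0.10 to -0.03. The list's camera adjusted p was 0.0715 without wild-type replicate 3, 0.0833 without knockout replicate 3 and 0.0705 without the arrays with high choroid plexus values, where 0 of its genes passed.

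Genes induced by activity or CREB moved little: 3 of 23 fell, 0 rose and 20 did not pass. The secretogranin gene Scg2 fell by 0.48, the immediate early gene Egr1 by 0.49 and the phosphatase gene Dusp1 by 0.25, while Nr4a1 changed by -0.22 (adjusted p = 0.0731). The median was -0.05 (camera adjusted p = 0.0285, 0.324 with an estimated correlation, fry 0.0202), and adjusted over the list alone 4 fell and 0 rose. The call of Dusp1 was lost whichever array was left out (adjusted p up to 0.140), and the list's camera adjusted p was 0.107 without wild-type replicate 3 and 0.0967 without the arrays with high choroid plexus values.

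Of 15 acetyltransferases and CREB coactivators, 2 fell, 0 rose and 13 did not pass. The acetyltransferase gene Kat7 fell by 0.18 and the CREB coactivator gene Crtc3 by 0.21. Crtc1 changed by -0.19 (adjusted p = 0.0903), Kat6b by -0.12 (adjusted p = 0.253) and Ep300, the closest relative of Crebbp and named outside the rule, by 0.08 (adjusted p = 0.413). The median was -0.06 (camera adjusted p = 0.0484, 0.421 with an estimated correlation, fry 0.1004), and adjusted over the list alone 3 fell and 0 rose. Both falls were lost whichever array was left out. The list's camera adjusted p was 0.0795, 0.0999, 0.0863 and 0.0889 without wild-type replicate 1, wild-type replicate 2, knockout replicate 2 and knockout replicate 3, and 0.162 without the arrays with high choroid plexus values.

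Of 12 p53 target and cell death genes, 1 fell, 0 rose and 11 did not pass. The receptor gene Eda2r fell by 0.40, and its call was lost without wild-type replicate 1, 2 or 3 or knockout replicate 3 (adjusted p = 0.0792, 0.0838, 0.0853 and 0.0756). The cell cycle inhibitor gene Cdkn1a changed by -0.18 (adjusted p = 0.110), Bbc3 by -0.15 and Ccng1 by 0.15. The median was 0.04, the mean -0.02 and the test's direction downward (camera adjusted p = 0.865, 0.901 with an estimated correlation). Adjusted over the list alone, 1 fell and 0 rose.

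Of 14 Purkinje cell genes, 1 rose, 1 fell and 12 did not pass: the homeobox genes Lhx5 and Lhx1 changed by 0.40 and -0.38, the calcium-binding protein genes Calb1 and Pvalb by 0.16 (adjusted p = 0.0577) and 0.36 (adjusted p = 0.281). The list's median was 0.06 (camera adjusted p = 0.0730). Its camera adjusted p was 0.0148 without wild-type replicate 2 and 0.0361 without knockout replicate 3, and Lhx5 lost its call without wild-type replicate 2 (adjusted p = 0.0588) or knockout replicate 1 (0.0553). Of 8 inhibitory interneuron genes 0 passed, with 0.30 for Tfap2b (adjusted p = 0.0762) and 0.17 for Gad1 (median 0.12, camera adjusted p = 0.0790, 0.00139 without knockout replicate 3, where 2 rose). Of 15 Bergmann glia and astrocyte genes, 2 rose, 1 fell and 12 did not pass. Gfap, the intermediate filament of astrocytes, rose by 0.45 (SE 0.07, adjusted p = 0.00459), whichever array was left out. Gdf10 rose by 0.20 and the glutamate transporter Slc1a2 fell by 0.30. The call of Gdf10 was lost without wild-type replicate 1 or 3 or knockout replicate 1 or 2 (adjusted p = 0.147, 0.112, 0.104 and 0.117), and that of Slc1a2 was lost whichever array other than knockout replicate 1 was left out (adjusted p up to 0.162). The glial list's median was 0.07 (camera adjusted p = 0.0514, 0.0413 without wild-type replicate 1 and 0.0102 without knockout replicate 3). Without the arrays with high choroid plexus values the Purkinje, interneuron and glial lists passed, with camera adjusted p = 0.0433, 0.00300 and 0.00743, in a fit that holds 1 knockout array. With an estimated correlation over all 6 arrays their adjusted p was 0.421, 0.446 and 0.421. Adjusted over the list alone, 2 Purkinje cell genes rose and 1 fell, 0 interneuron genes passed, and 2 glial genes rose and 1 fell.

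Of 14 microglia genes, 2 rose, 0 fell and 12 did not pass. Fcer1g, an immune receptor chain, rose by 0.52, and the complement gene C1qb by 0.34, while Cd68 changed by 0.41 (adjusted p = 0.0671) and Trem2 by 0.17. The median was 0.10 (camera adjusted p = 0.00309, 0.421 with an estimated correlation, fry 0.140), and adjusted over the list alone 3 rose and 0 fell. With the choroid plexus mean as a covariate the median was 0.19. It was 0.21 without the arrays with high choroid plexus values, a fit that holds 1 knockout array. Fcer1g lost its call without wild-type replicate 1 (adjusted p = 0.0824) or 2 (0.0671), and C1qb lost its call whichever array other than knockout replicate 3 was left out (adjusted p up to 0.136). The number that rose was 0 without wild-type replicate 1 or 2 and 1 without knockout replicate 1 or 2, and the list's camera adjusted p was 0.0571 without knockout replicate 2. Of 12 endothelial and pericyte genes 0 passed (median 0.02, mean -0.02, camera adjusted p = 0.807), with -0.39 for Slco1a4, -0.14 for Flt1 and 0.15 for Vwf. Only 2 of 11 red blood cell genes had a probe set of their own, Slc4a1 at 0.13 and Hemgn at 0.01, and 0 passed (median 0.07, camera adjusted p = 0.572). Of 14 brainstem and midbrain neuron genes, 1 fell, 0 rose and 13 did not pass: Slc17a6, a vesicular glutamate transporter that young granule neurons express too, fell by 0.72 (SE 0.07, adjusted p = 0.000385), while Hoxa2 and Hoxb4 of the hindbrain changed by -0.21 and -0.16 (median -0.06, camera adjusted p = 0.164). Adjusted over the list alone, 0 endothelial and 0 red blood cell genes passed and 1 brainstem gene fell. With dim genes left out, Slc17a6 was the only brainstem gene still measured, so that list says little about brainstem tissue.

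Choroid plexus genes differed between arrays more than between groups. Ttr, the abundant transthyretin of this tissue and named outside the rule, read 12.30, 8.08 and 8.91 on the wild-type arrays and 13.77, 9.19 and 13.92 on the knockout arrays. Over the 10 genes of the list the mean deviation from wild type was 0.43, -0.26 and -0.17 on the wild-type arrays and 1.42, -0.16 and 2.03 on the knockout arrays. None of the 10 passed with limma; their log2 changes included 1.77 for Sostdc1 (SE 0.56, adjusted p = 0.0970), 0.95 for Kcne2, 0.88 for Aqp1 and 0.86 for Calml4. The list's median was 0.94 (camera adjusted p = 0.000215, 0.421 with an estimated correlation, fry 0.277). Without knockout replicate 2, 9 of the 10 rose. Without the 3 arrays on which Ttr lay above 10 (wild-type replicate 1 and knockout replicates 1 and 3) the median was -0.00440. Ttr belongs to the list, so those arrays were picked by the list's own values. Of 12 meningeal fibroblast genes 0 passed (median 0.30, camera adjusted p = 0.000556, 0.421 with an estimated correlation, fry 0.298), although 5 rose and 0 fell adjusted over the list alone, and 4 rose without knockout replicate 1 and 1 without knockout replicate 2. Ogn changed by 0.69 (adjusted p = 0.0762), Col1a1 and Igf2 by 0.41 each and Col1a2 by 0.31. The meningeal mean was 0.06, 0.16 and 0.60 on the knockout arrays.

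Oligodendrocyte lineage genes were lower on the 2 knockout arrays with high choroid plexus values. The list's mean deviation was -0.44, -0.04 and -0.75 on knockout replicates 1, 2 and 3, and between -0.05 and 0.04 on the wild-type arrays. Of 12 genes, 1 fell, 0 rose and 11 did not pass: Mog, a myelin protein, fell by 0.71 (SE 0.18, adjusted p = 0.0415), while Olig1, Mbp and Pdgfra changed by -0.53, -0.39 and -0.15. The median was -0.42 (camera adjusted p = 1.76e-05, 0.421 with an estimated correlation, fry 0.172), and adjusted over the list alone 9 fell and 0 rose. Mog lost its call without wild-type replicate 1 or 2 or knockout replicate 1 or 3 (adjusted p = 0.156, 0.145, 0.112 and 0.0851), leaving 0 falls, and 9 genes fell without knockout replicate 2. Without the 3 arrays with high choroid plexus values the list's camera adjusted p was 0.929.

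**Figure D3:**
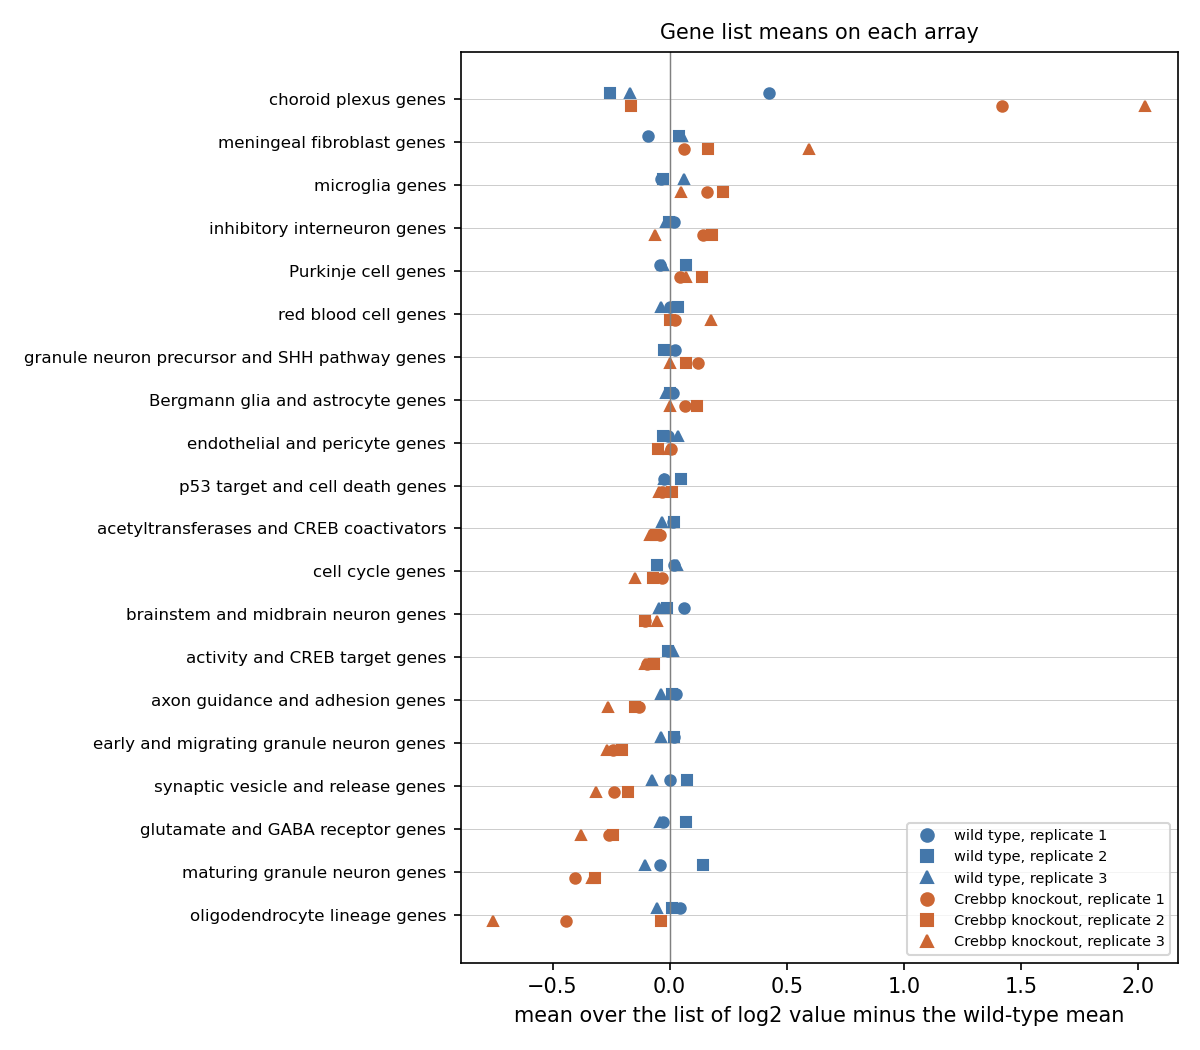
Mean over each of the 20 gene lists of the log2 value minus the wild-type mean, on each array; blue is wild type, orange knockout, and circles, squares and triangles are replicates 1, 2 and 3. All 3 knockout arrays lie below all 3 wild-type arrays for the early and maturing granule neuron, synaptic and receptor lists. The same holds, mostly by less, for the axon guidance, activity, acetyltransferase and brainstem lists. All measured genes of the brainstem list but 1 are dim. Within the knockout group the choroid plexus list ranges from -0.16 to 2.03 and the oligodendrocyte list from -0.75 to -0.04.

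The sex-linked genes split both groups. Xist, expressed from the inactive X chromosome, read 12.27, 12.32 and 5.74 on the wild-type arrays and 5.79, 6.45 and 12.30 on the knockout arrays, and the Y-linked genes Uty, Kdm5d and Eif2s3y ran the opposite way, so each group held more than 1 animal. The labels give no sex, and none of the 4 genes passed between the groups with limma (unadjusted p from 0.163 to 0.336).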

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

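All tests of explanations in this part were chosen after the result was seen, except the one over splits of the arrays and the one on near-identical copies. Among the 17824 probe sets without a single gene symbol, which enter no comparison above, 133 were higher and 92 lower in the knockout at an adjusted p under 0.05 with limma. They were picked out because they hold a signal in data outside the genes compared, and their genes are not named here.

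The 1479 genes past the threshold came from the real grouping, and the highest count of the 9 other splits of the 6 arrays into 3 and 3 was 4. Each other split mixes wild-type and knockout arrays, so a difference between the groups widens the spread within its sides. Low counts there would follow from a group difference of any cause. 1 of the 10 splits gave as many genes as the real one, which is itself, and 10 splits are too few for a share under 0.05.

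The early and maturing granule neuron lists were lower in the knockout (adjusted p = 0.324 for both with an estimated correlation), while in the precursor list 3 genes rose, 2 fell and the list did not pass (adjusted p = 0.0790). The precursor list did pass upward after repeated quantile normalization (camera adjusted p = 0.0436). A loss of granule-lineage cells of every stage would lower precursor and maturing genes alike, but the precursor list minus the maturing list was 0.42 higher in knockout (0.33 to 0.53 on the knockout arrays, -0.17 to 0.11 on the wild-type arrays). The precursor list itself shifted by 0.06, so most of this gap is the fall of the maturing list. Members of the precursor list went both ways, so its mean does not count precursors. A loss of granule-lineage cells is therefore not excluded. The precursor list also holds SHH pathway genes that other cells express. Dilution by choroid plexus or meningeal tissue would lower the Purkinje, interneuron and Bergmann glia lists as much, but these shifted by 0.0777 while the maturing list shifted by -0.35. A share of cells moved from maturing towards precursor stages, lower transcription of these genes in each cell without CREBBP, and a difference in age between litters may each give this pattern, and whole tissue does not separate them. Cell cycle genes were not higher in the knockout: 3 of 29 fell, 0 rose and the median was -0.06. Their list was called lower (camera adjusted p = 0.00374), though not with an estimated correlation (adjusted p = 0.446).

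Choroid plexus genes stood higher on 2 of 3 knockout arrays and 1 of 3 wild-type arrays. Uneven carry-over of this tissue at dissection is a candidate explanation: the list ranged over 2.19 within the knockout group, more than the difference of 1.09 between the group means, and the groups overlapped. Of the list, Ttr reached 13.92, where the highest value of any probe set on that array was 14.26. A growth of choroid plexus in some knockout animals stays open and was not tested. A link to oligodendrocyte genes stays open too. Their list mean was lower on the 2 knockout arrays with high values (-0.44 and -0.75), but not on wild-type replicate 1 (0.04).

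Several of the larger changes lay beside each other in the genome: among genes with a change of at least 0.5, 17 pairs were direct neighbours, where 10000 shuffles gave 3.86 on average and at most 12. Neighbours were counted again without predicted and small RNA genes, and without pairs whose symbols match up to the first digit. This gave 6 pairs, at the 95th percentile of shuffles (6, mean 2.63). They held Ifi203-ps with Mndal (-0.72 and -1.89) and still held related genes (Chrna3 with Chrnb4, Nefl with Nefm). Mid1 with Erdr1 became neighbours only in this count. A count this low is the outcome set beforehand for near-identical copies that share probes. The genes left out are not all such copies and probe sharing was not measured, so this stays open. DNA of another strain carried along with the floxed allele would change genes near Crebbp, of which 3 of the nearest 50 passed against 3.32 expected (one-sided Fisher's exact p = 0.655 for more and 0.573 for fewer). That count is too small to decide, and strain differences elsewhere in the genome were not tested.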

How the results depend on the processing

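Crebbp stayed lower and past the threshold in the alternatives run for it (not those on single probe sets or other thresholds), at -0.59 to -0.52, both values from fits without 1 array. The counts of 604 rises and 875 falls stayed within 1.5 times under a robust prior, without dim genes, after median centring or repeated quantile normalization, with array weights and with Xist as a covariate. They were 184 and 310 without a trend in the prior variance, 138 and 160 with a log2 change of at least 0.5, and 313 and 459 with each probe set tested on its own. At an adjusted p under 0.1, 1023 genes rose. Leaving out 1 array gave 199 to 478 rises and 366 to 800 falls. In 2 settings chosen after seeing the data, the choroid plexus mean as a covariate gave 253 and 290, and leaving out the 3 arrays with high choroid plexus values, where the lone knockout array is assumed to vary like the wild-type arrays, gave 112 and 124, of which 85 and 116 were among the original genes. The cause of these losses was not tested. After each group's gene means were subtracted, same-numbered arrays of different groups correlated at 0.01, 0.03 and -0.13. Arrays with different numbers correlated at -0.14 to 0.12, and not every array correlated best with its own number. These values gave no sign that the numbers pair the samples, but so few arrays cannot settle it. With the replicate number as a block 723 genes rose and 1078 fell, and 5 lists were higher and 9 lower.

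Of the 20 lists, 3 were higher and 9 lower. 5 were higher after repeated quantile normalization and with array weights, 2 to 7 when 1 array was left out (7 to 9 lower), and 5 higher and 5 lower without the 3 arrays with high choroid plexus values (2 and 5 of them among the original lists). With the choroid plexus mean as a covariate 4 were higher and 6 lower (1 and 6 among the original lists). The oligodendrocyte, meningeal, activity and acetyltransferase lists lost their calls there (camera adjusted p = 0.0908 for each). The choroid plexus list did too (0.795), and its median was -0.00440 without the 3 arrays. Neither setting tests that list, since the covariate is its own mean and the 3 arrays were picked by its member Ttr. With an estimated correlation 0 were higher and 0 lower, and fry gave 0 higher and 5 lower. Apart from the choroid plexus list, the cause of these shifts was not tested. Of 69 named genes past the threshold, 53 stayed past it whichever array was left out. The named genes were picked for large changes or small p, which favours this. Of all genes past the threshold, 191 of 604 rises and 363 of 875 falls stayed without wild-type replicate 1. No measure of background came with the values, so what dim signals limit is unknown beyond the fit without dim genes (732 rises and 1035 falls).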

Other observations

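The 2 tests of explanations in this part were fixed before their results were seen; the gene families were chosen after the data had been examined. Families were formed from the start of the gene symbols, and 241 with at least 10 genes were tested with camera as an exploration; 8 passed, and 0 of these with an estimated correlation (adjusted p = 0.983 for each). Of 32 Cfap genes, which encode proteins of motile cilia and flagella, 5 rose and 0 fell, with 0.76 for Cfap69 and 0.53 for Cfap300 (median 0.16, camera adjusted p = 7.91e-05). Their median stood at 0.13, 0.11 and 0.17 on the knockout arrays and at 0.03, -0.04 and 0.00 on the wild-type arrays. Of 14 Cacna genes, which encode subunits of voltage-gated calcium channels, 6 fell and 0 rose, with -0.52 for Cacna2d3, -0.49 for Cacna1c and -0.49 for Cacna1e (median -0.24, camera adjusted p = 0.000672). The Rpl genes of the large ribosomal subunit passed upward (45 genes, median 0.09, camera adjusted p = 0.00294): Rpl34 and Rpl14 rose by 0.62 and 0.22, and Rpl3 fell by 0.89. The 26 Snora genes, small nucleolar RNAs, passed upward too, with 4 rises and 1 fall (median 0.18, camera adjusted p = 0.00294). Of 11 annexin genes 3 rose and 0 fell, Anxa5 by 0.47. Of 78 genes whose symbol starts with Ppp, 8 fell and 0 rose, of 17 synaptotagmin genes 3 fell and 0 rose, Syt9 by 0.52, and of 21 Sox genes 2 fell and 0 rose, Sox12 by 0.42. Without the 3 arrays with high choroid plexus values the annexin, Ppp, synaptotagmin and Sox families did not pass (adjusted p = 0.101, 0.371, 0.349 and 0.900), and the Rpl and Snora families did (0.0475 and 0.00477). All genes in this paragraph were named after their values were seen.

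Choroid plexus carries cilia, so uneven carry-over of it was tested as a possible explanation of both the cilia and the calcium channel changes. Without the 3 arrays with high choroid plexus values the medians were 0.14 and -0.23, close to those over all arrays, and both families still passed. That is the outcome set beforehand as arguing against carry-over, but it rests on 1 knockout array, which excludes nothing, so the explanation stays open for both.

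Neighbouring genes changed together in a few places. Chrna3 and Chrnb4, subunits of one nicotinic receptor, rose by 0.80 and 0.79, and the neurofilament genes Nefl and Nefm fell by 0.63 and 0.57. Thsd7b, beside Cxcr4, rose by 0.72. Ifi203-ps and its neighbour Mndal, the largest named fall, changed by -0.72 and -1.89. The neighbours Glra3 and Hpgd went opposite ways, at -0.53 and 0.54. The predicted gene Gm3893 had the smallest p of all genes tested, from 8.14 ± 0.05 to 10.88 ± 0.06 (log2 change 2.74, SE 0.05, adjusted p = 6.46e-09), and its neighbour Fam205a2 rose by 0.99. These pairs were picked after their values were seen.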
